A study of Homo sapiens with 4 samples.

How the data were processed

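RNA was measured in 4 libraries from 293T-REx cells, an established human embryonic kidney cell line with a doxycycline-controlled repressor for inducible transgenes. Per the labels' protocols, cells were induced with 1 µg/ml doxycycline for 24 h, held with a photo-activatable compound at 10 µM for 2 h at 37 °C and irradiated at 365 nm with 500 mJ/cm2. RNA was then extracted, biotinylated RNA was captured on streptavidin beads, and strand-marked libraries were made from randomly primed fragments. The induced transgene was the U1 snRNP protein SNRNP70 with an MSA tag (the sample) or an NFH tag (the control). From each line the labels give 1 input library and 1 streptavidin precipitate, called IPL here for in vivo proximity labelling.

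The authors deposited whole-number read counts per gene together with RPKM values (reads scaled by gene model length in kilobases and by library size), per the file headers. The deposited counts are not normalized. The deposited RPKM values equal the count divided by a length and by a library denominator, and the denominators recovered from the snRNA genes were 14476230 reads in NFH input, 7504571 in NFH IPL, 17106796 in MSA input and 11477654 in MSA IPL. Counted gene reads made up 33.5%, 34.0%, 33.8% and 32.5% of these denominators. Bowtie and the hg19 genome are named in the submitters' processing notes. The Bowtie version, the treatment of reads that map to several places, the minimum mapping quality and the use of strand in counting are not given in the sources used here. How reads of repeated genes were placed can change every value of the multi-copy RNAs described in the report.

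The table held 52358 entries for 52335 genes after 23 repeated entries were dropped. Gene names, biotypes and hg19 coordinates were taken from the table, whose gene set is that of Ensembl release 65 per the deposited table's name, and 26237 genes carried an HGNC symbol and 4351 only a family name. The 37 mitochondrial genes were listed with 0 reads in every library. Total gene reads were 4855941 in NFH input, 2553395 in NFH IPL, 5783196 in MSA input and 3735034 in MSA IPL. At these depths 1 RPKM in a gene model of 1 kb stands for 14.5, 7.5, 17.1 and 11.5 reads.

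Ratios were computed as log2((RPKM + 1)/(RPKM + 1)), a scale that understates the change of low genes, over the 9853 genes with a mean of at least 1 RPKM. The 5 contrasts were IPL over input in MSA cells, the same in NFH cells, the double ratio (the first minus the second on the log2 scale), MSA IPL over NFH IPL, and MSA input over NFH input. Each group held 1 library, so the comparisons have no replicate check and no p-value across genes is given. Folds of single genes and summed families are ratios of RPKM without a pseudocount, with 95% Poisson intervals on the counts. Intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Shares of reads have exact Clopper-Pearson intervals. No fold is given for a library with 0 reads.

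A list of genes was described by its median and by the percentile of that median among 10000 random lists of the same size, matched on mean RPKM in 20 bins. A percentile under 2.5 or over 97.5 is called standing apart, as a description of these 4 libraries. In all, 30 gene lists were fixed before the data were examined, as were the contrasts, the thresholds and the rule for named genes. That rule took SNRNP70, the 10 highest and 10 lowest genes of each contrast with a mean of at least 5 RPKM (5 and 5 for the inputs; for the double ratio only genes whose precipitate ratio had the same sign), and the 3 most abundant members of each list (all 9 for U1). XIST and Y-linked genes were left out, and 1 gene that the rule takes is not reported here. Genes chosen otherwise are said to be so where they appear. The fixed design assumed RPKM values alone. The deposited counts were used for intervals, for scaling factors and for a minimum of reads, and no count model was fitted.

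Alternatives were a pseudocount of 0.1 or 5 RPKM, no minimum level or a minimum of 5 RPKM, median-centred libraries, libraries scaled to equal RPKM sums, random lists drawn from small RNA genes and summed lists. Chosen after the data were seen were scaling by the TMM factors of edgeR, random lists matched on gene model length, the summed U1 genes as 1 value, and a minimum of 100 reads over the 4 libraries. The number of 4-fold differences expected from counting alone was taken from 20 Poisson draws in which each gene had the same level in both cell lines. GC content and exon number came from GENCODE release 29 and were used without its coordinates.

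The procedure was tested on simulated data for the double ratio, with counts drawn for 9927 genes. The changed genes were drawn from those with at least 5 RPKM and 100 reads, so recovery at lower levels was not tested. Of 100 genes changed 8-fold, 100% passed the 4-fold threshold, with a median log2 ratio of 2.91. Of 100 genes changed 2-fold, 0% passed, and of 9727 unchanged genes 0.596% passed. Of 200 lists of 9 unchanged genes 5.5% stood apart, as did 100% of 50 lists of 9 genes changed 2-fold. Simulated genes were drawn independently, unlike copies that share reads, so these rates need not hold for the U1 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.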

Results

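RNA near the U1 snRNP protein SNRNP70 was profiled in 293T-REx cells, an established human embryonic kidney line, by photochemical labelling in living cells followed by streptavidin capture and sequencing. Cells carried SNRNP70 with an MSA tag, which the series names as the sample, or with an NFH tag, which it names as the control. From each line there was 1 input library and 1 precipitate of biotinylated RNA (IPL). Gene reads numbered 4855941 in NFH input, 2553395 in NFH IPL, 5783196 in MSA input and 3735034 in MSA IPL. Each of the 4 groups was 1 library, so every difference below compares libraries without a replicate check, and the intervals cover counting error only. The question named by the series is which RNAs lie close to tagged SNRNP70, and the ratio of IPL to input in MSA cells over the same ratio in NFH cells (the double ratio) addresses it most directly. Unless marked as folds, ratios of lists and of their sums below are on the log2 scale.

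SNRNP70 itself, the gene of the tagged protein (ENSG00000104852, chromosome 19, 49588465 to 49611869, plus strand, hg19), was far more abundant in the MSA precipitate than in any other library. Its RNA stood at 167.9 RPKM in NFH input (95% interval 164.7 to 171.1), 365.7 in NFH IPL (359.2 to 372.2), 180.1 in MSA input (177.0 to 183.1) and 1121.5 in MSA IPL (1112.3 to 1130.7). The inputs differed by 1.07-fold (1.05 to 1.10) and the precipitates by 3.07-fold (3.01 to 3.13). In MSA cells the precipitate held 6.23-fold (6.11 to 6.35) the input level, against 2.18-fold (2.12 to 2.24) in NFH cells, and the double ratio was 2.86-fold (2.77 to 2.95). SNRNP70 ranked 4 and 3 among protein-coding genes in the NFH and MSA inputs, and 3 and 2 in the NFH and MSA precipitates. The values add the endogenous gene and the transgene, whose reads were not separated. The NFH precipitate ratio was log2 1.12, where the median of all genes was 0.74. It was -0.13 after TMM scaling (gene median -0.09), 2.03 with equal RPKM sums (1.27) and 0.34 with median-centred libraries (-0.04).

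**Figure D1:**
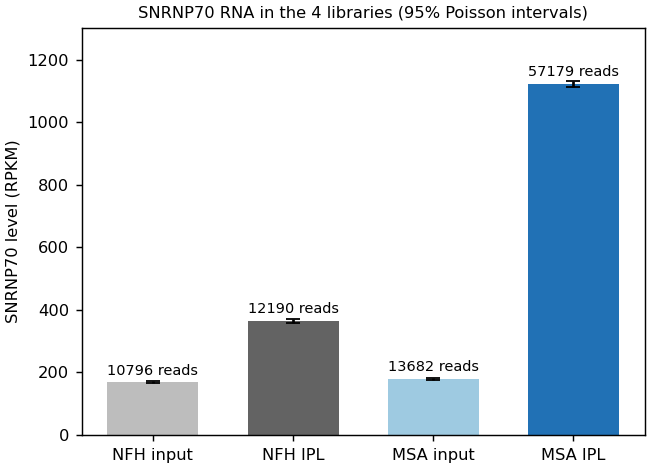
SNRNP70 RNA in RPKM (vertical axis, from 0) in each of the 4 libraries, with bars for the values and error bars for 95% Poisson counting intervals. MSA IPL stands at 1121.5 RPKM, above NFH IPL at 365.7 and the inputs at 167.9 and 180.1.

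U1 snRNA, the RNA of the particle that SNRNP70 belongs to and that recognises 5' splice sites, was higher in the MSA precipitate than in the NFH precipitate. Summed over the 9 U1 genes, it was 2.6-fold (2.52 to 2.69) higher in MSA IPL than in NFH IPL, while the inputs differed by 1.27-fold (1.25 to 1.29). The double ratio was 2.05-fold (1.97 to 2.12). All 9 genes lay above the gene median, with a list median of 0.99 on the log2 scale at percentile 99.84 of random lists. RNU1-3 (ENSG00000207513, chromosome 1, 16993280 to 16993443, minus strand) had a double ratio of 2.17-fold (1.96 to 2.41) and RNU1-2 (ENSG00000207005, chromosome 1, 17222475 to 17222638, plus strand) one of 1.99-fold (1.76 to 2.25).

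Sequence-related U1-like copies behaved in the same direction. Of 135 copies 43 were tested, 33 lay above the gene median, and their median log2 double ratio was 1.27 (percentile 100). Their summed reads gave 2.54-fold (2.31 to 2.79), with 2.29-fold (1.77 to 2.96) for RNU1-10P and 1.39-fold (1.07 to 1.80) for RNU1-12P. Copies of U1 can share reads, and within 6 genes (RNU1-1, RNU1-3, RNU1-5, RNU1-6, RNU1-8 and RNU1-9) and within 3 (RNU1-2, RNU1-4 and RNU1-7) the reads were spread evenly in each library (chi-square p over the genes from 0.06 to 0.55). The 9 genes are therefore not 9 independent values. Their sum was placed as 1 value among the 493 single genes in the highest bin of mean RPKM. It sat at percentile 90.26 for the double ratio and 96.55 for the direct ratio of the precipitates, neither of which stands apart. That bin was not narrowed to the level of the sum, and single U1 genes alone had means of 886.9 to 1298 RPKM. The percentiles therefore do not show how the sum stands among genes of its own level.

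Relative to input, U1 snRNA was lower in both precipitates on the RPKM scale, and less so in MSA cells. The precipitate held 0.577-fold (0.567 to 0.587) the input level of U1 in MSA cells and 0.282-fold (0.273 to 0.291) in NFH cells. The list medians of -0.77 and -1.76 lay 1.58 and 2.51 log2 units under the gene medians of 0.81 and 0.74, with 0 of 9 genes above them in either line. Random lists of like level had medians of -0.61 and -0.59, and among them the U1 medians had percentiles of 44.07 and 7.25. Among lists of small RNA genes alone the MSA value had percentile 99.09. With the RPKM sums of the libraries made equal, the MSA median became 0.46, where the gene median was 1.56.

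Among the other major spliceosomal snRNAs, U2, U4 and U5 did not share the U1 difference when their reads were summed, while U6, with few reads, had 1.44-fold (1.16 to 1.80). The gene median of the log2 double ratio was 0.08, 0.00 after TMM scaling and 0.30 with equal RPKM sums, and double ratios are read relative to it. U2, U4, U5 and U6 snRNA together, which pair with the branch site or form the tri-snRNP, had a double ratio of 0.838-fold (0.805 to 0.874), and U1 genes and copies exceeded them by 2.52-fold (2.39 to 2.65). U2 had a summed double ratio of 0.644-fold (0.576 to 0.721) and a median of -0.58 (percentile 0, 15 tested, 1 above the gene median). For U5 the values were 0.620-fold (0.572 to 0.674) and -0.64 (percentile 0.12), with RNU5A-1 at 0.728-fold (0.628 to 0.843) and RNU5B-1 at 0.539-fold (0.449 to 0.647). Both differences lay partly in the inputs, where summed U2 was 1.31-fold (1.26 to 1.35) and U5 1.32-fold (1.29 to 1.35) higher in MSA cells. Their levels in MSA IPL were 0.843-fold (0.757 to 0.938) and 0.819-fold (0.756 to 0.887) those in NFH IPL. RNU4-2 and RNU4-1, which carried most U4 reads, stood at 0.882-fold (0.816 to 0.954) and 0.991-fold (0.914 to 1.07). The U4 list median of 0.37 (percentile 99.89) turned to -0.10 when the tested members were summed.

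Among the snRNAs of the minor spliceosome, which removes a rare class of introns, RNU11 had a double ratio of 2.49-fold (1.74 to 3.56) and RNU12 of 1.46-fold (1.12 to 1.90). RNU4ATAC of the same spliceosome had 0.778-fold (0.605 to 1.00). The list median was 0.69 (percentile 100, 13 of 16 above the gene median), and the summed reads gave 1.25-fold (1.09 to 1.42). For this list the inputs stood apart, lower in MSA cells (-0.32, percentile 0), and the precipitates did not (0.10, percentile 76.85). RNU11 rested on 39 reads in NFH IPL and 157 in MSA IPL.

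Small RNAs outside the spliceosome mostly lay near the gene median of 0.08 when summed. The log2 double ratio was -0.03 (-0.09 to 0.03) for 7SK RNA, the scaffold that holds P-TEFb inactive, -0.05 (-0.10 to -0.01) for box C/D snoRNA, -0.07 (-0.17 to 0.02) for box H/ACA snoRNA and 0.09 (-0.10 to 0.28) for scaRNA of Cajal bodies. Y RNA had 0.36 (0.23 to 0.48), 7SL RNA of the signal recognition particle 0.15 (-0.02 to 0.32), and the RNase MRP and vault RNAs -0.34 (-0.41 to -0.26). RMRP, the RNA of RNase MRP, stood at 0.799-fold (0.757 to 0.844), and SNORD3C, a U3 snoRNA gene, at 0.877-fold (0.830 to 0.926). By their medians, Y RNA (0.67), 7SK RNA (0.39) and the spliceosomal U6 snRNA (0.24) stood apart above random lists (percentile 100 each), and rRNA copies (-0.52, percentile 0), scaRNA (-0.13, percentile 0.57) and box C/D snoRNA (0.00, percentile 1.95) below. For Y RNA and U6 the inputs were lower in MSA cells (-0.31 and -0.09, percentiles 0 and 2.45), and the precipitates did not stand apart (0.00 for each, percentiles 3.22 and 12.16). For 7SK the input median was lower (-0.19, percentile 0) and the precipitate median higher (0.12, percentile 97.85), but summed 7SK reads were 1.10-fold (1.09 to 1.12) higher in MSA input, and RN7SK itself 1.37-fold (1.34 to 1.40). H/ACA snoRNA (0.15), 7SL RNA (0.15), U7 snRNA (0.04) and the RNase and vault RNAs (-0.29) did not stand apart.

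These calls depended on the random lists used. Against lists of small RNA genes only, U4, U6, 7SK, scaRNA and minor spliceosome snRNA no longer stood apart, and neither did U4, U5, U6, 7SK, scaRNA and box C/D snoRNA against lists of like gene model length. U1 genes, U1-like copies, U2 and rRNA copies stood apart against both kinds of list. Without a minimum level, where most members had no reads, each of these small RNA and rRNA lists except the U1 genes had a median of 0.

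**Figure D2:**
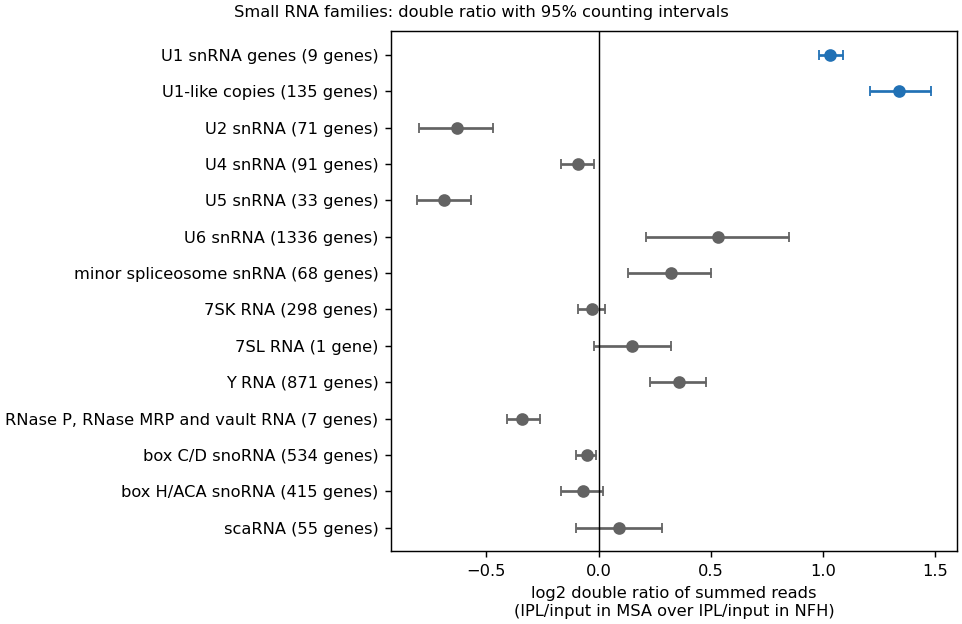
Log2 double ratio of summed reads (horizontal axis) for 14 small RNA families, with 95% counting intervals as bars and the U1 families in blue; the line marks 0. U1 genes (1.03) and U1-like copies (1.34) lie above all others plotted, and U2 (-0.63) and U5 (-0.69) lie lowest.

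Messenger RNAs varied little in the double ratio on the scale of RPKM + 1, which understates the change of low genes. Among 6845 protein-coding genes with at least 100 reads the SD was 0.24 on that log2 scale, 9 genes were at least 2-fold higher and 1 was at least 2-fold lower. The folds below carry no pseudocount and can be larger, as for HOXC13 with 1.03 on the log2 scale and 3.87-fold (1.85 to 8.08). Besides SNRNP70, the 9 included H2AFZ, which encodes the histone variant H2A.Z (2.53-fold, 1.92 to 3.33), SNAPC5, a subunit of the complex that drives snRNA gene transcription (2.70-fold, 1.45 to 5.03), and LSM7, a member of the Lsm ring that binds U6 (2.82-fold, 1.52 to 5.26). The others were GLTSCR2 (3.03-fold, 1.92 to 4.77), KRBA2, HOXC13, C9orf16 and EEF1B2, and the lower gene was HAUS1 (0.370-fold, 0.166 to 0.825). Of the 9, 5 were lower in MSA input than in NFH input with intervals below 1: LSM7 at 0.525-fold (0.347 to 0.796), GLTSCR2 at 0.606-fold (0.438 to 0.837), EEF1B2 at 0.596-fold (0.443 to 0.803), C9orf16 at 0.504-fold (0.316 to 0.805) and HOXC13 at 0.555-fold (0.320 to 0.963). The precipitates of LSM7 and GLTSCR2 differed by 1.48-fold (0.935 to 2.35) and 1.83-fold (1.33 to 2.52). H2AFZ differed by 1.19-fold (0.956 to 1.47) between inputs and 3.00-fold (2.52 to 3.56) between precipitates. These genes were chosen after their values were seen. The double ratio has MSA input in its denominator, so choosing by it favours genes with low MSA input through counting error. The input intervals are thus no independent support. No counts expected from counting alone were drawn for the 2-fold threshold.

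Of the messenger RNA lists, ribosomal protein mRNAs and immediate early genes stood apart above random lists in the double ratio. Ribosomal protein mRNAs had a median of 0.24 (percentile 99.97), with 54 of 79 above the gene median, RPL19 at 1.47-fold (1.27 to 1.70) and RPL27 at 1.44-fold (1.17 to 1.78). Their direct ratio of precipitates was 0.21 (percentile 100, 67 of 79 above the gene median) and that of inputs -0.01 (percentile 83.65). Immediate early genes, many of which encode transcription factors induced within minutes of a stimulus, had a median of 0.35 (percentile 99.8, 11 of 15 above). Their inputs were lower in MSA cells (median -0.22, percentile 0.18, 1 of 15 above the gene median), and their precipitates did not stand apart (0.10, percentile 78.57). JUN had an input ratio of 0.755-fold (0.664 to 0.859) and a double ratio of 1.34-fold (1.14 to 1.59), and MYC had 0.737-fold (0.621 to 0.875) and 1.47-fold (1.15 to 1.88). The immediate early call ended at a minimum of 5 RPKM (percentile 94.92), and both calls ended against lists of small RNA genes (percentile 62.08 and 51.3). Small RNA genes are another RNA class, so the latter comparison does not decide whether these lists differ from other mRNAs.

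The remaining messenger and long non-coding lists lay close to the gene median. The mRNAs of spliceosomal Sm and U1 proteins had a median double ratio of 0.01 (16 tested), splicing regulators with detained introns 0.15 (23), nuclear long non-coding RNAs 0.12 (7), snoRNA host genes 0.20 (10), p53 targets 0.19 (10), heat shock genes 0.11 (12), secretory pathway mRNAs 0.04 (19), abundant cytosolic mRNAs 0.16 (18) and endogenous biotin enzymes 0.16 (3), and none stood apart. SNRPC, which encodes another U1 protein, stood at 1.01-fold (0.732 to 1.38) and MALAT1 at 0.985-fold (0.954 to 1.02). Replication-dependent histone mRNAs had -0.04 (percentile 0.68, 18 of 57 above the gene median). That call ended against lists of like model length (percentile 2.74) and without a minimum level (percentile 6.1). It also ended against lists of small RNA genes (percentile 2.84), which are another RNA class. All 13 markers of other cell types were under the 1 RPKM minimum, and of the mitochondrial list only a nuclear copy of MT-ATP8 with 59 reads had any (double ratio 1.04, percentile 95.53).

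Both precipitates differed from their inputs in RNA class in a like way. Protein-coding genes took 22.9% of gene reads (95% Clopper-Pearson interval 22.8% to 22.9%) in NFH input and 52.4% (52.4% to 52.5%) in NFH IPL, and 21.5% (21.4% to 21.5%) in MSA input and 57.6% (57.5% to 57.6%) in MSA IPL. rRNA pseudogenes took 55.3% (55.3% to 55.3%) and 30.4% (30.4% to 30.5%) in NFH input and IPL, and 55.9% (55.8% to 55.9%) and 25.3% (25.3% to 25.4%) in MSA. The share of snRNA was 2.42% (2.41% to 2.43%) and 0.378% (0.371% to 0.386%) in NFH input and IPL, and 2.58% (2.56% to 2.59%) and 0.699% (0.690% to 0.707%) in MSA. That of snoRNA was 2.92% (2.91% to 2.94%) and 0.367% (0.359% to 0.374%) in NFH, and 2.75% (2.74% to 2.77%) and 0.356% (0.350% to 0.362%) in MSA. Over 9853 genes the median log2 ratio of IPL to input was 0.81 in MSA cells (SD 0.82) and 0.74 in NFH cells (SD 0.87). That median was -0.09 in both lines after TMM scaling and 1.56 and 1.27 with equal RPKM sums, so lists are given relative to other genes.

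**Figure D3:**
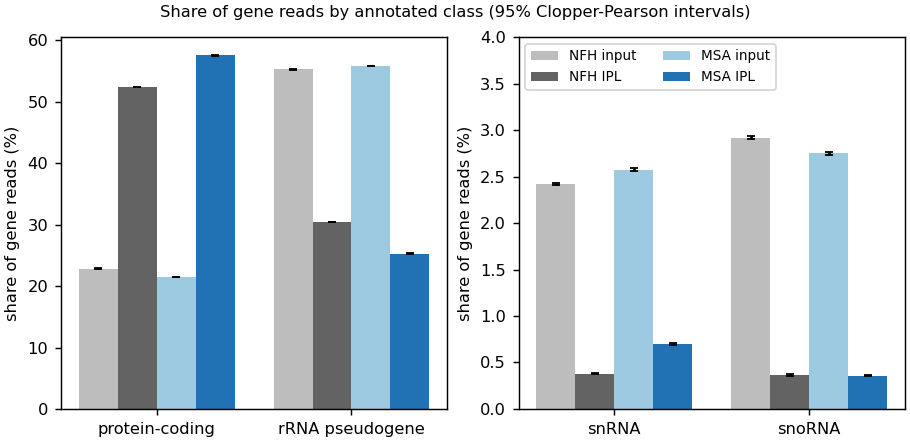
Percent of gene reads (vertical axes, from 0, with a wider scale on the left) by RNA class in each of the 4 libraries, with bars for the shares and error bars for 95% Clopper-Pearson intervals. Protein-coding genes take 52.4% and 57.6% in the NFH and MSA precipitates and 22.9% and 21.5% in the inputs.

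Long RNAs kept in the nucleus were high in the precipitates of both lines. Nuclear long non-coding RNAs had median ratios of 1.51 in MSA cells (percentile 99.99) and 1.37 in NFH cells (percentile 99.97), with MALAT1, a nuclear speckle RNA, at 3.43-fold (3.36 to 3.50) and 3.48-fold (3.4 to 3.57). NEAT1, the scaffold of paraspeckles, stood at 3.08-fold (2.95 to 3.21) and 2.54-fold (2.42 to 2.67). Splicing regulators with detained introns, whose transcripts are partly kept in the nucleus, had 1.42 and 1.28 (percentile 100 in each), with 23 of 23 above the gene median in both lines. SRSF1 had 3.23-fold (3.00 to 3.47) in MSA and 2.79-fold (2.55 to 3.06) in NFH cells, SRSF2 3.13-fold (2.83 to 3.47) and 2.69-fold (2.39 to 3.04). Heat shock genes had 1.12 in MSA cells (percentile 99.59) and 0.84 in NFH cells (percentile 90.25). That difference between lines, the double ratio of 0.11, did not stand apart.

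Replication-dependent histone mRNAs, which lack a poly(A) tail, were depleted in both precipitates. Their medians were -0.78 in MSA and -0.52 in NFH cells (percentile 0 in each), and 0 of 57 lay above the gene median in either line. HIST1H1E stood at 0.612-fold (0.555 to 0.675) and 0.640-fold (0.574 to 0.715), and HIST1H3B at 0.480-fold (0.409 to 0.565) and 0.723-fold (0.609 to 0.860). Most small RNA lists lay low as well. Box C/D snoRNA (96 tested), box H/ACA snoRNA (97), U2 (15), U4 (21), U5 (9) and U6 snRNA (65) had percentiles of at most 0.03 in both lines. U1 genes (-0.77 and -1.76) and 7SL RNA (-0.73 and -0.88, percentiles 49.37 and 45.01) did not stand apart, though they too lay under the gene medians. Their random lists of like level had low medians, -0.61 and -0.59 for U1 and -0.70 and -0.71 for 7SL. For box C/D snoRNA these were 0.66 and 0.57, so percentiles are not comparable between lists. U7 snRNA, which acts in histone mRNA processing, lay high (1.27 and 1.33, percentiles 99.93 and 100). It rested on 6 reads in NFH input, 12 in NFH IPL, 4 in MSA input and 20 in MSA IPL. SNORD3C stood at 0.0851-fold (0.0821 to 0.0882) and 0.0970-fold (0.0932 to 0.101), and RNU4-2 at 0.0773-fold (0.0733 to 0.0814) and 0.0876-fold (0.0827 to 0.0928). Ribosomal protein mRNAs (0.77 and 0.50) and Sm and U1 protein mRNAs (0.84 and 0.86) did not stand apart in either line. Abundant cytosolic mRNAs had 0.78 and 0.61 (percentiles 98.96 and 97.6), above lists of like level though below the gene medians. Those lists had medians of only 0.13 and 0.03, against 0.70 and 0.63 for the ribosomal protein list, so this call does not show a gain over other mRNAs.

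**Figure D4:**
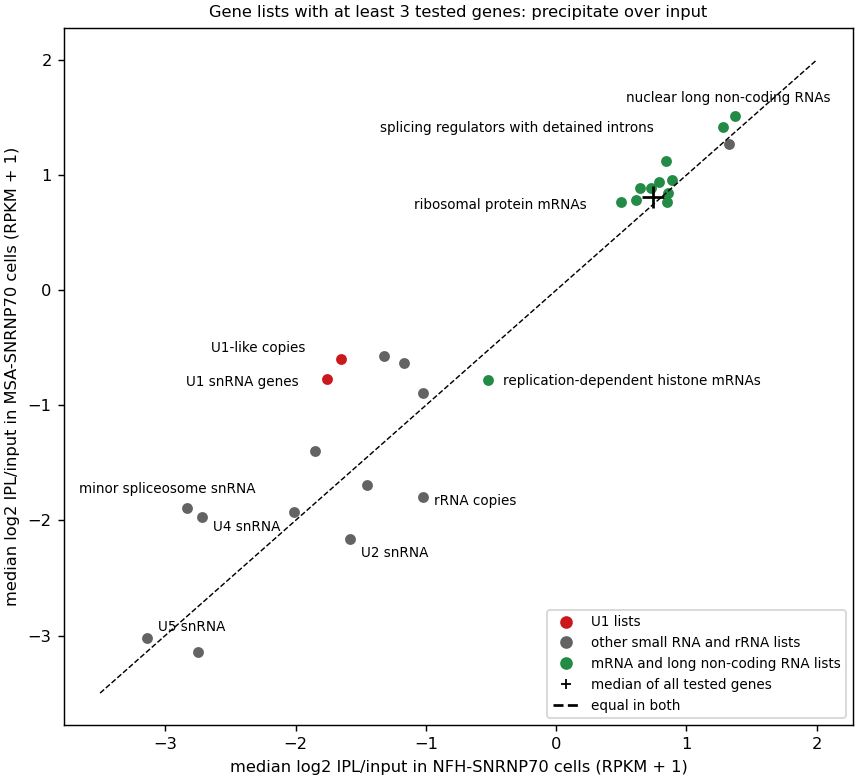
Median log2 ratio of IPL to input (RPKM + 1) in NFH cells (horizontal axis) and MSA cells (vertical axis) for each list with at least 3 tested genes; points are lists, the cross marks the median of all genes and the dashed line equal values. U1 genes lie at -1.76 and -0.77, above the line, and U2 at -1.58 and -2.16, below it.

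Single genes with extreme ratios were mostly repeated small RNA and rRNA loci. In the double ratio 124 genes were at least 4-fold higher and 52 at least 4-fold lower, where counting alone gave a mean of 25.2 (at most 30) and 24.4 (at most 33). With at least 100 reads these counts were 15 and 10 of 8067. Among genes of at least 5 RPKM whose precipitate ratio had the same sign, the 10 highest held 0 protein-coding genes, and 6 of them had 3 or fewer reads in a compared library, among them a U4 copy (ENSG00000201379) with 42 reads in NFH input, 1 in NFH IPL, 7 in MSA input and 37 in MSA IPL. ENSG00000242597, an rRNA pseudogene on chromosome 10, was read deeply (3648, 226, 551 and 410 reads in that order). Its level in MSA input was 0.128-fold (0.117 to 0.14) that in NFH input, while the precipitates differed by 1.19-fold (1.01 to 1.4). Under the same rule the lowest were RN5-8S5, a 5.8S rRNA locus (124, 196, 272 and 12 reads), and ENSG00000243092, an rRNA pseudogene on chromosome 12 (10194, 10529, 19334 and 1047). The share of higher genes among those 4-fold apart was 70.5%, 63.9% after TMM scaling and 75.3% with equal RPKM sums.

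In IPL over input, SNRNP70 was the only protein-coding gene among the 10 highest in MSA cells, and H2AFZP1, a processed copy of H2AFZ, was another (27 reads in MSA input and 131 in MSA IPL). The 10 lowest in MSA cells were all small RNA or rRNA loci, such as RNU4-7P with 1860 reads in MSA input and 15 in MSA IPL. In NFH cells the 10 highest held 0 protein-coding genes, and 9 of the 10 lowest had 3 or fewer reads in a compared library. Counts of genes at least 4-fold apart were 59 higher and 228 lower in MSA cells and 39 higher and 311 lower in NFH cells. With at least 100 reads they were 11 and 128 in MSA cells and 2 and 141 in NFH cells, and no counts expected from counting alone were drawn for these ratios.

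Comparing the precipitates directly, 45 genes were at least 4-fold higher and 24 at least 4-fold lower in MSA IPL, where counting alone gave means of 13.6 and 11.4. With at least 100 reads the counts were 5 and 2 of 8067. U1 genes (median 1.36, percentile 100) and U1-like copies (1.04, percentile 100) were the highest lists. U2 (-0.31, percentile 0.03) and U5 (-0.31, percentile 0.46) stood apart below, as did histone mRNAs (-0.12, percentile 0), rRNA copies (-0.03, percentile 1.93) and, by its median only, U7 snRNA (-1.14, percentile 0). The tested U7 members summed to -0.39 (-1.96 to 1.18), and all 200 U7 loci, with 12 reads in NFH IPL and 20 in MSA IPL, to 0.12 (-0.91 to 1.16). Ribosomal protein mRNAs (0.21), box H/ACA snoRNA (0.21), U4 (0.20, percentile 98.83) and 7SK RNA (0.12, percentile 97.85) stood apart above by their medians. When tested members were summed, U4 was lower in MSA IPL (-0.26, -0.34 to -0.18) and the interval of H/ACA snoRNA included 0 (0.04, -0.05 to 0.13). Tested rRNA copies summed to -0.40 (-0.41 to -0.38). DNAJB1, which encodes a cochaperone of HSP70 and was chosen after its value was seen, was 3.23-fold (2.65 to 3.96) higher in MSA IPL and 1.71-fold (1.39 to 2.11) higher in MSA input.

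The input libraries of the lines were close for messenger RNAs on the scale of RPKM + 1 and differed at repeated loci. Of 6845 protein-coding genes with at least 100 reads, 0 were at least 2-fold higher in MSA input and 1 was at least 2-fold lower, MTRNR2L1 (0.391-fold, 0.375 to 0.407), a nuclear copy of mitochondrial rRNA sequence, and the SD was 0.16. Over all 9853 genes 17 were at least 4-fold higher and 50 at least 4-fold lower, where counting alone gave at most 4 and 5. The share of higher genes among these was 25.4%, and 42.3% with a pseudocount of 0.1. The extremes were small RNA and rRNA copies, such as a 5S rRNA copy (ENSG00000199525) with 13 reads in NFH and 733 in MSA input, and another (ENSG00000200310) with 468 and 32. rRNA copies (0.69, though 0.09 with an interval of 0.08 to 0.10 when summed) and U2 (0.43) had input medians at percentile 100, and U1 genes (0.38) were at percentile 97.32. By their medians 15 of 29 lists stood apart between inputs, as many as in the double ratio (15), against 11 in the direct ratio of precipitates. U1-like copies, U2, box C/D and H/ACA snoRNA, scaRNA, rRNA copies, histone mRNAs and snoRNA host genes were higher in MSA input, and U4, U6, minor spliceosome snRNA, 7SK, Y RNA, immediate early genes and the nuclear MT-ATP8 copy lower. When the tested members were summed, the direction turned for 7SK (0.15, 0.12 to 0.17), box C/D snoRNA (-0.10, -0.11 to -0.09) and scaRNA (-0.08, -0.16 to 0.00). The intervals of summed U1-like copies (0.02, -0.03 to 0.07), histone mRNAs (0.02, -0.02 to 0.05) and snoRNA host genes (0.03, -0.08 to 0.13) included 0. HSP90AA1, a heat shock chaperone, was 1.35-fold (1.26 to 1.43) higher in MSA input, and HSPA1A was 0.865-fold (0.818 to 0.914), with the heat shock list not apart (0.00, percentile 62.79).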

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

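At 6 repeated loci, among the genes that the rule for named genes takes, the 95% counting interval of the IPL to input ratio lay wholly above the median of all genes (log2 0.81 in MSA and 0.74 in NFH cells) in one line and wholly below it in the other. The median is on the scale of RPKM + 1 and the intervals carry no pseudocount. Against the medians with a pseudocount of 0.1 (1.20 in MSA and 1.10 in NFH cells) 4 of the 6 kept this, and the U3 copy (1.13 to 2.39 in MSA cells) and the rRNA pseudogene on chromosome 12 (0.96 to 1.03 in NFH cells) did not. Each locus is 1 gene in 1 library per group, and the difference between the lines was not tested in any of the 6. Reads are given in the order NFH input, NFH IPL, MSA input and MSA IPL, and values are log2 double ratios.

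A scRNA pseudogene on chromosome 8 (ENSG00000242170, 126282846 to 126283144) had 4.96, with 62, 5, 12 and 72 reads. A U4 copy on chromosome 6 (ENSG00000201379, 121863632 to 121863772) had 6.08, with 42, 1, 7 and 37 reads. A U3 copy on chromosome 9 (ENSG00000252299, 90989184 to 90989274) had 3.39, with 40, 6, 29 and 66 reads. Toward the NFH line, a scRNA pseudogene on chromosome 5 (ENSG00000239390, 143520444 to 143520681) had -3.09, with 12, 35, 9 and 2 reads. The 5.8S rRNA locus RN5-8S5 on chromosome 2 (ENSG00000202174, 133010727 to 133010878) had -5.34, with 124, 196, 272 and 12 reads. An rRNA pseudogene on chromosome 12 (ENSG00000243092, 34372314 to 34372611) had -4.62, with 10194, 10529, 19334 and 1047 reads. In MSA cells the interval of its IPL to input ratio ran from -3.72 to -3.54 on the log2 scale, and in NFH cells from 0.96 to 1.03.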

How the results depend on the processing

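Scaling by TMM, lists of like model length, U1 as 1 summed value and the minimum of 100 reads were chosen after the data were seen, and the other settings before the data were examined. Under every scaling, pseudocount and minimum level tried, the U1 double ratio (0.87 to 1.30) and the direct ratio of precipitates (1.31 to 1.58) kept their direction and stood apart. As 1 summed value among single genes of the highest level bin they were 1.03 (percentile 90.26) and 1.38 (percentile 96.55) and did not stand apart. There 1 value is set against the spread of single genes, which were not matched to the level of the sum. The U1 ratio of IPL to input in MSA cells, -0.77, had percentile 99.09 among small RNA genes, the opposite side from its main percentile of 44.07, because small RNAs were lower still. Without a minimum level it had percentile 0.71, and the NFH value of -1.76 had 0.05. Summed, the NFH value was -1.83.

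Here the RPKM of tested members were summed, which weights abundant members, while sums in the Results are of reads and can differ. The sign turned for 3 lists that stood apart, U4 (-0.10), 7SK (-0.04) and scaRNA (0.03), and for H/ACA snoRNA (-0.05), which did not. ScaRNA stayed under the gene median of 0.08, and its counting half-width of 0.19 covered its list median of -0.13. Summing also moved minor spliceosome snRNA to 0.29, Y RNA to 0.33, ribosomal protein mRNAs to 0.34, histone mRNAs to -0.13, nuclear long non-coding RNAs to 0.00 and heat shock genes to 0.18. U6 (0.24) fell to percentile 18.41 among small RNA genes, and U7 was 0.96 (percentile 99.93) after TMM scaling, and the cause was not tested. Of the other lists, 12 lost their call without a minimum level, 3 at 5 RPKM, 7 against small RNA genes, 7 against lists of like length and 1 with a pseudocount of 5. Some of the lists that lost it against small RNA genes are mRNA lists, for which that pool is another RNA class. Gained calls numbered 1 under each of 5 RPKM, no minimum level, a pseudocount of 0.1 and equal RPKM sums. U7 and biotin enzymes had no tested member at 5 RPKM, Y RNA had no matching small RNA genes, and markers of other cell types gave no value at 1 RPKM.

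Counts of 4-fold differences moved with the pseudocount and the minimum level. For the double ratio, higher and lower counts were 268 and 150 with a pseudocount of 0.1, 26 and 12 with 5, 42 and 19 at 5 RPKM, and 15 and 10 with 100 reads. For the inputs they were 85 and 116, 3 and 13, 6 and 22, and 2 and 8 in that order, with 10 higher at equal RPKM sums and 38 higher after TMM scaling. Fewer genes were tested at 5 RPKM (1978) and with 100 reads (8067), and the cause of the other moves was not tested.

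SNRNP70 in NFH input, NFH IPL, MSA input and MSA IPL was 122.9, 505.7, 124.0 and 1811 at equal RPKM sums, and 258.2, 235.7, 290.8 and 700.6 after TMM scaling. Its log2 double ratio stayed between 1.40 and 1.83. No paired analysis was possible because each group held 1 library.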

Other observations

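The gene groups and single genes of the next paragraph, the tests of U1 snRNA and the comparison of SNRNP70 between inputs were chosen after the results were seen. The tests of abundant mRNAs, length, GC content and exon number were set before theirs.

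Genes of the ZNF zinc finger family, mostly repressors of transcription, lay high in both precipitates and in the double ratio. Over 161 tested genes the median ratio of IPL to input was 1.04 in MSA cells and 0.87 in NFH cells, and the double ratio was 0.18 (percentile 100 in each), with 109 above the gene median in the double ratio. ZNF317 stood at 1.92-fold (1.41 to 2.61) and ZNF34 at 1.75-fold (1.06 to 2.89) in the double ratio. PCF11, a factor of mRNA 3' end cleavage, stood at 1.62-fold (1.32 to 1.99), with precipitate over input of 4.24-fold (3.74 to 4.8) in MSA cells and 2.61-fold (2.22 to 3.07) in NFH cells. H2AFZ and 2 processed copies, which can share reads, were 2.65-fold (2.09 to 3.38) when summed. Replication-independent histone genes as a group of 8 did not stand apart (0.20, percentile 83.15). Single-exon protein-coding genes (296 tested) stood apart above in the double ratio (0.12, percentile 97.58) and the direct ratio of precipitates (0.09, percentile 99.71). Relative to input they stood apart below in NFH cells (0.65, percentile 0.11) and not in MSA cells (0.75, percentile 3.12). Genes annotated as pseudogenes, processed or not (1680 tested), lay low in both precipitates (0.61 and 0.55, percentile 0 in each) and near the gene median in the double ratio (0.09, percentile 85.02).

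The higher level of U1 snRNA in the MSA precipitate was weighed against reads shared among copies, a bias against short RNAs and more U1 in the MSA cells. Summed over all 144 U1 genes and copies the log2 double ratio was 1.08 (1.03 to 1.13). This sum does not depend on how reads were placed among the 144. It was bound to be high, since genes (1.03) and copies (1.34) each were, so it is no separate test of shared reads. Reads placed at other loci are not covered. Other genes of 100 to 220 nt had a median of -0.18 (spread 0.75, 192 genes) against 0.99 for U1, although 21 of them reached the U1 median. The inputs differed by 0.30 (0.28 to 0.32) and the precipitates by 1.38. A candidate explanation is labelling of U1 snRNA near MSA-tagged SNRNP70, a hypothesis that stays open because each group is 1 library and any difference in handling goes with the tag.

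SNRNP70 RNA was weighed in the same way. The inputs differed by 0.10 on the log2 scale and the precipitates by 1.61, which argues against a higher starting level. Among 21 other protein-coding genes of at least 50 RPKM the highest double ratio was 0.63 (MTRNR2L1, median 0.09) against 1.51 for SNRNP70, so a general gain of abundant mRNAs is not seen. The RNA may be labelled close to newly made tagged protein or held near it in the nucleus, and these hypotheses, along with differences in handling that go with the tag, were not tested.

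In both precipitates small RNAs and histone mRNAs were low and long nuclear RNAs high, and length and GC content of the RNA were weighed as technical causes. Across 10763 genes, which are not independent replicates, the Spearman correlation between model length and the NFH ratio was 0.24 (0.20 in MSA cells, 0.15 and 0.10 among protein-coding genes). The correlation with GC content was -0.25 over 9421 protein-coding genes (-0.15 in MSA cells), so neither trend is excluded as a part of the pattern. For histone mRNAs and splicing regulators, the values argue against either trend alone as the whole cause. Among protein-coding lists of like length, and again of like GC content, histone mRNAs stayed at percentile 0.00 and splicing regulators at percentile 100. Length and GC content were not matched together, and small RNAs and nuclear long non-coding RNAs were not tested in this way. Nuclear retention of long RNAs and the missing poly(A) tail of histone mRNAs may add to the pattern. No biological explanation was tested because the pattern was in both tag groups.

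A further hypothesis was that mRNAs with more exons, and so more splice sites for U1, would have a higher double ratio. Across 9421 protein-coding genes the Spearman correlation between exon number and the double ratio was -0.06, so no such rise was seen. Counting error in single genes weakens such a correlation, so the hypothesis is not decided by it. The correlation with GC content was 0.12 for the double ratio, -0.28 for the input ratio and -0.07 for the direct ratio of precipitates. A GC trend between the inputs may thus enter the double ratio, and what caused that trend was not tested.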
